A study of Homo sapiens with 2 samples.

How the data were processed

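The series holds 1 PROX1 ChIP-seq library and 1 input DNA library from SW480R cells. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was fragmented with an enzymatic kit and immunoprecipitated with 5 µg of a goat antibody against human PROX1, and libraries were made from 10 ng of DNA. Per the series' design text, 3 independent immunoprecipitations were pooled before sequencing, so their spread is not in the data. The authors' peak list for the ChIP library against input was used. No file of its own was used for the input library, and it enters through the folds alone.

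The build is hg18, per the submitters' processing notes. The aligner, the peak caller, its threshold, the treatment of repeated reads and the full library depths are not given in the sources used here. The list has no header, so the meaning of its columns was read from the values. The deposited tag counts per peak are whole numbers from 13 upward and are not normalized. The deposited fold was read as a ratio of ChIP tags to input tags, scaled by 1 constant, which held exactly for narrow peaks but not for all wide ones. The deposited p-value falls in steps as the fold rises, with no overlap between the fold ranges of its 91 distinct values, and its highest value is 0.00099. It is printed as 0 for 23 peaks, and a p-value cannot be told from a q-value there. Each peak had to reach a fold of 13.03, so a place with many input tags needs proportionally more ChIP tags to be listed. All widths are multiples of 20 bp. Whether starts count from 0 or 1 is unknown, and coordinates are printed as the list gives them. Only peaks are listed, so depth outside them, and the level at places without a peak, could not be assessed. Intervals are for counts of peaks and cover counting error only, with neighbouring peaks taken as independent. Reads without molecular identifiers are also not independent molecules, which bears on the tag counts.

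Input tags behind each peak were inferred as tags times the constant (1.0025 after rounding, taken from peaks over 100 tags at the lowest input) divided by the fold. The result was a whole number, within 0.02, for 91.6% of all peaks and for 100% of the 16891 peaks of 60 bp or narrower, but for 70.1% of wider ones. Where it was not whole, the inferred input is an approximation. The lowest inferred value, 1, was found in 71.8% of peaks and may stand for 0 or 1 input tags, so folds there are set by the tag count. This inference was made after the values were seen.

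Chromosome lengths of hg18 came from the R package GenomeInfoDb 1.38.1 and contig placements, which give length without assembly gaps, from IRanges 2.36.0 (R 4.3.3). Statistics were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The share of peaks on each of 24 nuclear chromosomes was tested against its share of length with an exact two-sided binomial test, with Benjamini-Hochberg adjustment at 0.05. Because neighbouring peaks cluster, 574 blocks of 5 Mb, with densities over length without gaps, were also shuffled between chromosomes 10000 times, for which the smallest possible unadjusted p is 0.0001. Clusters were runs of peaks whose edges lay within 10 kb. Peak centres were placed at random over the contigs of their own chromosome 1000 times, and a window of 1 Mb was called dense when it held more peaks than any window of these placements. Strong peaks were those at 2 times the lowest fold or more. Shares were compared with Fisher's exact test. The 33 mitochondrial peaks were left out of the chromosome, cluster and window comparisons.

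The methods were tested on simulated data with 23417 peaks. In 20 simulations of peaks per chromosome, 40 of 40 chromosomes raised 1.3 times and 40 of 40 lowered to 0.7 times were recovered. In 20 further simulations with no change, 1 of 480 chromosomes was called. For dense windows, 20 of 20 windows planted with 60 additional peaks were found with 0 others. For the share of peaks with raised input, 20 of 20 shares raised from 4% to 12% and 1 of 20 unraised shares were called. Inferred input was recovered for 100% of the simulated peaks whose fold reached the level of the list. Their folds were built from whole inputs with the same formula, so this checks the arithmetic and rounding only. Simulated peaks were drawn independently of each other, without the clustering of the real list. The rates of false calls therefore do not carry over to clustered peaks.

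The comparisons of peak number, chromosomes and clusters, and the alternatives of the authors' threshold, merging distance and highest tag counts, were fixed before the data were examined. Those on length without gaps or to the last peak, blocks, strong shares, the share of peaks with a neighbour, dense windows and inferred input were added afterwards. The rule for named items covered PROX1 itself, the 10 genes at the highest-ranked peaks, the 5 genes with the most peaks and the 2 best-ranked genes of each of 17 gene lists with 405 entries. No hg18 annotation or genome sequence was used here, and coordinates of another build were not mixed with those of the list. The rule was therefore applied to the 10 highest-ranked peaks in place of genes, ordered by p-value and then by fold. The comparisons of peak position relative to genes, gene lists, strength at lists and by position, genes with several peaks, and the PROX1 motif were not analysed here, and clusters of peaks stand in for the last but one.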

Results

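PROX1 is a homeobox transcription factor that directs lymphatic, hepatic and lens development and is expressed in a subset of colorectal tumours. Its sites on chromatin were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in SW480R cells, a subpopulation of SW480, an established human colorectal adenocarcinoma line. One pooled library from 3 independent immunoprecipitations was set against 1 library of input DNA, the chromatin before immunoprecipitation, to ask where in the genome of these cells PROX1 sits. The deposited list held 23450 peaks on the hg18 build, with 897512 tags inside them. The full depth of either library is not given in the sources used here. There was 1 library of each kind, so no difference between conditions and no replicate spread could be measured. Each test below treats peaks as features of this pair of libraries, and each interval is an exact (Clopper-Pearson) 95% binomial interval that covers counting error only. The binomial tests, Fisher's exact tests and intervals count neighbouring peaks as independent, so they can overstate the certainty. Coordinates are printed as the list gives them, since nothing in it shows whether starts count from 0 or 1. Peaks are described by position alone, because no hg18 gene annotation was used here.

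Most PROX1 peaks were listed as narrow, and most folds lay in the low part of their range. The median peak held 25 tags (interquartile range 17 to 44, range 13 to 5495) and had a fold over input of 19.05 (interquartile range 15.04 to 28.4, range 13.03 to 435.08). The lowest and the median width were both 40 bp, and the widest peak spanned 560 bp. These widths are the list's own, in multiples of 20 bp. The span over which tags were counted is not given, so they do not measure the extent of the signal. Peaks of 80 bp or wider made up 28.0% of the list and had a median of 32 tags, against 24 tags in the 57.2% of peaks that were 40 bp wide and 18 tags in the 14.8% that were 60 bp wide. A fold of 26.06 or more, which is 2 times the lowest fold in the list, was found in 7101 of the 23417 nuclear peaks (30.3%), and these are called strong peaks below. A fold of 100 or more was reached by 228 peaks, of which 20 lay on chromosome 8 and 3 on the mitochondrial genome. The tag counts, folds and p-values are the authors' own and rank peaks within this list only.

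Chromosome 8 held 4 of the 10 highest-ranked peaks. The first, at 129209311 to 129209551, had 434 tags and the highest fold of the list, 435.08. On the same arm, 128296911 to 128296951 had 338 tags at a fold of 338.84, and 129258371 to 129258511 had 334 tags at a fold of 334.83. The other chromosome 8 peak of this group, at 8378471 to 8378511, had a fold of 230.57. Rank 2 went to the mitochondrial genome, where the peak at 7791 to 8091 had 5495 tags and a fold of 344.29. On chromosome 20, the peak at 29756091 to 29756231 had 264 tags and a fold of 264.66. Single peaks on chromosome 2 (29824711 to 29824751, fold 242.6) and chromosome 5 (1056571 to 1056611, fold 241.6) followed. The last members were on chromosome 19 (54763331 to 54763471, 496 tags, fold 222.55) and chromosome 21 (39927771 to 39927811, 220 tags, fold 220.55). Apart from the mitochondrial peak and that on chromosome 19, these 10 peaks had the lowest inferred input, 1. Their folds were therefore set by their tag counts.

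**Figure D1:**
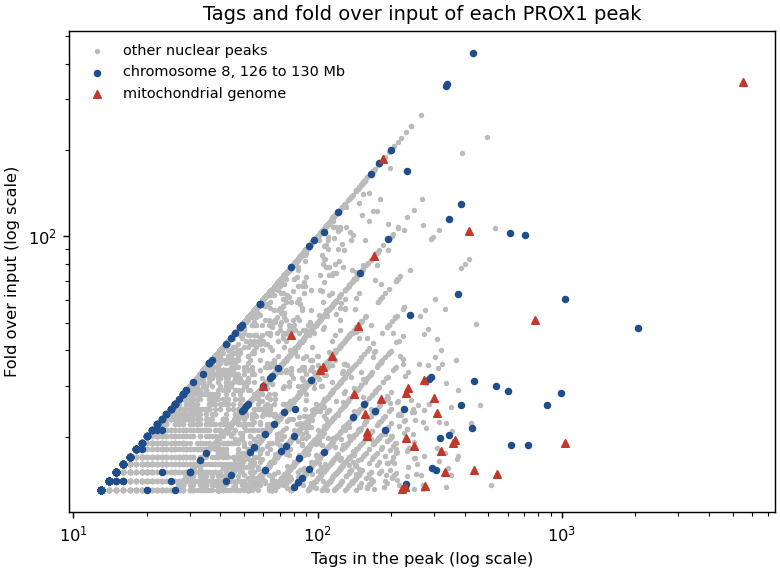
Tags in each peak (x axis, log scale) against fold over input (y axis, log scale), 1 point per peak. Nuclear peaks are grey, those at 126 to 130 Mb of chromosome 8 blue and those of the mitochondrial genome red triangles; the mitochondrial peak with 5495 tags lies farthest to the right and the chromosome 8 peak with a fold of 435.08 highest.

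PROX1 peaks were unevenly spread over the chromosomes. The nuclear genome held 7.60 peaks per Mb. Chromosome 17 held 13.4 peaks per Mb (95% interval 12.6 to 14.2), which is 1.76 times the number its length gives, and chromosome 20 held 12.5 (11.7 to 13.4), or 1.65 times. At the other end were chromosome 4 with 4.17 peaks per Mb (3.89 to 4.46, 0.548 times) and chromosome X with 3.23 (2.95 to 3.52, 0.425 times). Of 24 chromosomes tested, 7 held more peaks than their length gives, 5 held fewer and 12 did not pass the test (exact binomial test, two-sided, Benjamini-Hochberg adjusted). The adjusted p was 1.75e-64 for chromosome 17, 2.75e-38 for chromosome 20, 1.61e-82 for chromosome 4 and 1.43e-113 for chromosome X. The remaining higher chromosomes were 12 (9.87 peaks per Mb), 1 (9.15), 10 (9.10), 7 (8.73) and 2 (8.62), and the remaining lower ones 13 (6.75), 9 (6.17) and Y, where 1 peak was called. Over length without assembly gaps, 11 chromosomes were higher and 6 lower. Chromosome 13 was then at 0.983 times (adjusted p = 0.663, exact binomial test), 16, 19, 21 (1.36 times) and 22 (1.44 times) joined the higher ones, and 3 and 6 the lower ones. Neighbouring peaks are not independent. Over the same length, in a permutation test that shuffled 574 blocks of 5 Mb between chromosomes, 1 chromosome stayed higher (17, adjusted p = 0.0104) and 2 lower (4 and X, adjusted p = 0.0012 each), while chromosome 20 had an adjusted p of 0.0514.

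**Figure D2:**
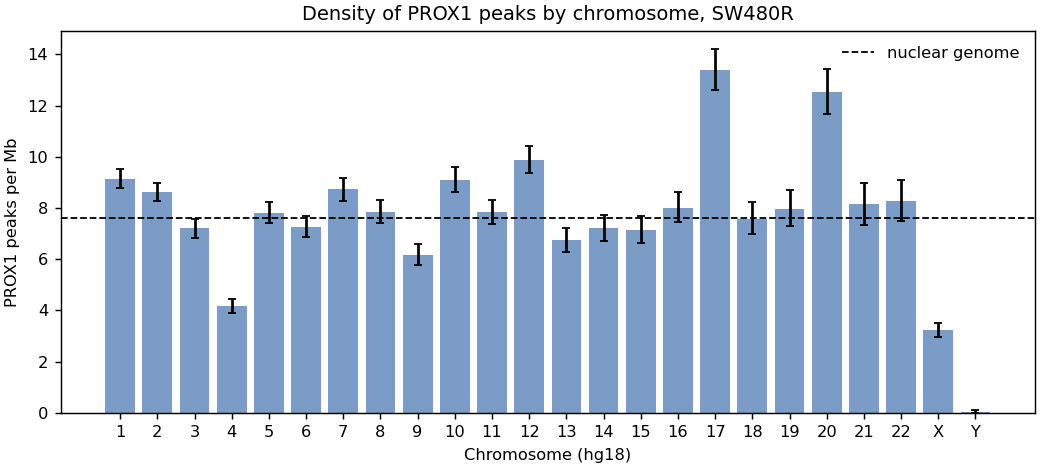
PROX1 peaks per Mb of hg18 length (y axis) on each chromosome (x axis); bars give the observed density, error bars the exact 95% binomial interval and the dashed line the nuclear genome at 7.60 peaks per Mb. Chromosomes 17 and 20 stand highest, and chromosomes 4, X and Y lowest.

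Strong peaks took a larger share on chromosome 20 (35.3%, interval 31.9 to 38.8) and chromosome 7 (33.8%, 31.3 to 36.3) than on the rest of the nuclear genome. Their share was smaller on chromosome 4 (25.7%, 22.7 to 28.9) and chromosome 8 (26.6%, 24.1 to 29.2). Each of these 4 differences had an adjusted p of 0.0277 (Fisher's exact test, two-sided, 24 chromosomes). The calls depended on the measure of strength: taking as many peaks with the most tags gave 6 higher and 4 lower chromosomes. None of the 24 passed Fisher's exact test among the nuclear peaks of the 11725 better-ranked ones or at a fold of 100 or more. At that fold chromosome 8 lay on the other side, with 1.74% of its peaks against 0.921% elsewhere (adjusted p = 0.278, Fisher's exact test).

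PROX1 peaks lay in clusters. A neighbour within 10 kb was found for 56.4% of nuclear peaks (interval 55.8 to 57.1), against a mean of 16.1% and a highest value of 17.2% in 1000 random placements on the same chromosomes. When each peak was placed at random within its own 1 Mb window, the mean was 26.2% and the highest value 27.4%. Part of the closeness was at short range, since 33.1% of nuclear peaks lay in runs joined within 1 kb. With peaks within 1 kb merged, 37.1% had a neighbour within 10 kb, against a highest random value of 14.4%. Whether peaks this close are separate sites or 1 site listed several times was not tested. Joining peaks within 10 kb gave 14752 places, of which 10173 held a single peak, 2651 held 2, and 1928 held 3 or more. Runs of 10 or more peaks numbered 42. The largest run lay at 128295451 to 128365591 of chromosome 8 and held 41 peaks with 4246 tags over 70.14 kb. It was followed by 129634751 to 129685791 of the same chromosome (29 peaks), 35221171 to 35281811 of chromosome 21 (22 peaks) and 43835651 to 43876091 of chromosome 19 (18 peaks). Next came 232791931 to 232822291 of chromosome 1 with 16 peaks and 92088411 to 92113251 of chromosome 7 with 15. Joining the nuclear peaks among the 11725 better-ranked peaks of the list in the same way gave 2082 runs of 2 or more, against 4579 for all nuclear peaks.

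Peaks in runs were stronger than peaks that stood alone. Strong peaks made up 24.0% of single peaks (interval 23.1 to 24.8), 34.1% of peaks in runs of 2 to 4 (33.2 to 35.0) and 38.7% of peaks in runs of 5 or more (37.0 to 40.4). The median fold was 18.04, 20.05 and 21.93 in these classes, and the median tag count 21, 28 and 31. The share in runs of 5 or more differed from that of single peaks with p = 6.06e-57 (Fisher's exact test, two-sided). Peaks of the same run were counted as independent here, so this p-value and the intervals can overstate the certainty. The comparison was not repeated with peaks within 1 kb merged, although 33.1% of nuclear peaks lay in runs joined at that distance. It therefore does not separate clustered sites from 1 site listed as several peaks.

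**Figure D3:**
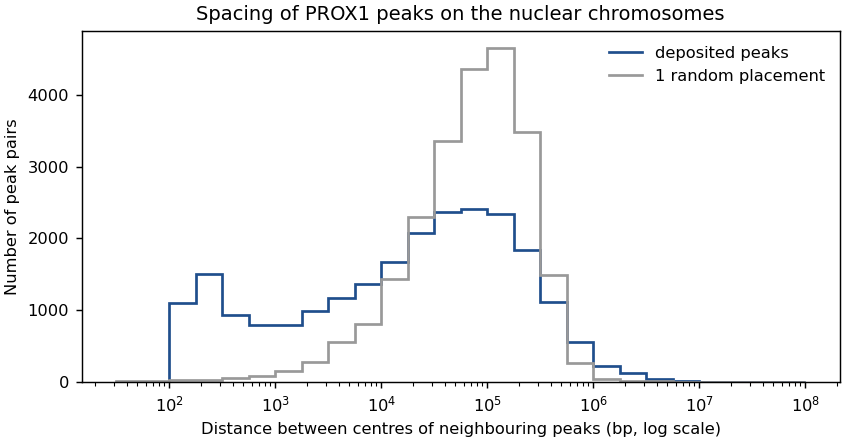
Distance between the centres of neighbouring peaks on the same nuclear chromosome (x axis, bp, log scale) against the number of neighbouring pairs (y axis), for the deposited peaks (blue) and 1 random placement of as many peaks (grey). The deposited peaks have many more pairs at distances under 10 kb, where 56.4% of peaks have a neighbour.

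Dense stretches of PROX1 peaks were found on several chromosomes. The densest 1 Mb window was 128 to 129 Mb of chromosome 8, with 121 peaks, and the windows 129 to 130 Mb (72 peaks) and 126 to 127 Mb (66 peaks) of the same chromosome were also among the 10 densest. The others of these 10 were 53 to 54 Mb of chromosome 14 (72 peaks), 35 to 36 Mb of chromosome 21 (71), 60 to 61 Mb of chromosome 17 (56), 10 to 11 Mb of chromosome 18 (53), 64 to 65 Mb of chromosome 2 (51), 74 to 75 Mb of chromosome 12 (50) and 67 to 68 Mb of chromosome 15 (49). In all, 73 windows held more than 30 peaks, the highest number in any window of 1000 random placements, and together they held 2876 peaks (12.3% of the nuclear list). With peaks within 10 kb counted once, 3 windows lay above the corresponding random limit of 22. With the nuclear peaks among the 11725 better-ranked ones, 27 lay above a limit of 21. Windows were chosen for description after their values were seen.

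One of the 10 densest windows differed from the rest of the nuclear genome in the strength of its peaks, and the windows were not tested against each other. On chromosome 14, 47.2% of the peaks at 53 to 54 Mb were strong (interval 35.3 to 59.3, against 30.3% elsewhere, adjusted p = 0.0286, Fisher's exact test over 10 windows). At 35 to 36 Mb of chromosome 21 the share was 43.7% (31.9 to 56.0) and the median tag count was 43, and this share did not pass (adjusted p = 0.0738, Fisher's exact test). The densest window of chromosome 8 had a share of 20.7% (13.8 to 29.0, adjusted p = 0.0738, Fisher's exact test). The other 7 windows had shares from 24.2% to 37.3% and did not pass.

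The stretch from 126 to 130 Mb of chromosome 8, on the long arm that also carries the MYC oncogene, held 281 peaks. This is 70.2 peaks per Mb and 9.24 times the genome rate, while the rest of chromosome 8 held 866 peaks at 6.09 per Mb. The stretch was not dense throughout, since its window at 127 to 128 Mb held 22 peaks, below the random limit of 30. Strong peaks made up 23.5% of the stretch (interval 18.7 to 28.9) against 30.4% of the other nuclear peaks (p = 0.0129, Fisher's exact test, two-sided). The direction turned among the highest folds: 13 of the 281 peaks (4.63%, 2.49 to 7.78) reached a fold of 100 or more, against 212 of the 23136 others (0.916%, p = 3.61e-06, Fisher's exact test). The number of input tags behind a peak was inferred from its tags and its fold. It was 5 or more in 11.7% of the peaks of the stretch (8.22 to 16.1) and in 4.33% of the others (p = 3.4e-07, Fisher's exact test). At an inferred input of 2 or more the shares were 22.8% and 22.7% (Fisher's exact p = 0.943), and at 10 or more they were 6.05% and 0.545% (p = 1.61e-12). Many peaks of the stretch lie side by side in runs and were counted as independent, so these p-values can overstate the certainty. The nuclear peak with the most tags lay in this stretch, at 128824591 to 128824631, with 2047 tags, a fold of 47.72 and an inferred input of 43. The bounds of the stretch were set after the peaks had been counted.

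**Figure D4:**
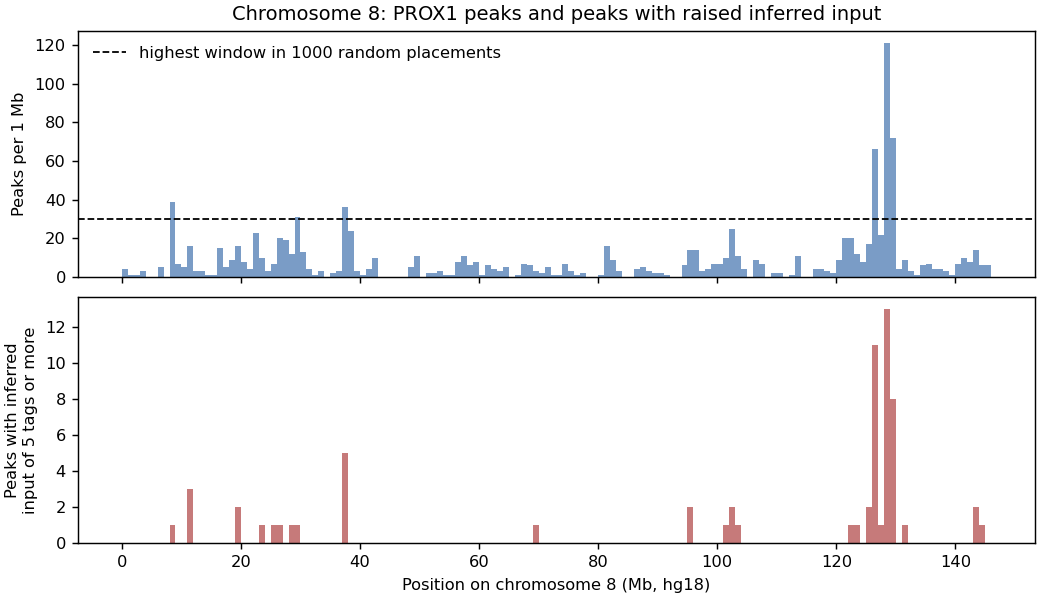
Upper panel, PROX1 peaks per 1 Mb window (y axis) along chromosome 8 (x axis, Mb, hg18), with the highest window of 1000 random placements, 30 peaks, as a dashed line; lower panel, peaks per window with an inferred input of 5 tags or more. Both panels are highest at 128 to 129 Mb, where 121 peaks were called and 13 of them had such an input.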

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

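Of the tests in this part, that of whether clusters account for the whole dense stretch of chromosome 8 and that of mitochondrial folds at raised input were chosen before their results were seen. The others, on input, strength, the outer windows, gaps and copy number, were chosen afterwards. The design has no groups to compare and names no biological explanation to test. Strength and copy number were tested within this pair of libraries alone.

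PROX1 peaks on the mitochondrial genome stood out as signal outside the chromosome comparison, with 33 peaks that held 14381 tags, 1.60% of all tags in peaks. Their median tag count was 230, against 25 in nuclear peaks, and the peak at 7791 to 8091 held 38.2% of the mitochondrial tags. Many copies of mitochondrial DNA may raise tags in both libraries: an inferred input of 5 or more was found in 72.7% of these peaks (95% interval 54.5 to 86.7) and in 4.42% of nuclear ones (Fisher's exact p = 1.05e-25). Strong peaks made up 51.5% of mitochondrial peaks and 30.3% of nuclear ones (Fisher's exact p = 0.0125), and whether copies alone give this stays open. The test planned for it, among peaks with an inferred input of 5 or more, gave 33.3% (8 of 24) against 11.3% (117 of 1035, Fisher's exact p = 0.00431). That is the outcome written beforehand as speaking against copies alone. Without the peak at 7791 to 8091 the share was 30.4% (Fisher's exact p = 0.0126). The test still does not decide, because input is the denominator of the fold and choosing peaks by it moves the share of strong peaks. The share was 11.3% in the chosen nuclear peaks against 31.2% in the other nuclear peaks (Fisher's exact p = 1.3e-49). It was also lower in the chosen mitochondrial peaks, at 33.3% against 51.5% of all mitochondrial peaks. Whether the choice moved both groups by the same amount was not tested.

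The stretch at 126 to 130 Mb of chromosome 8 held 281 peaks, 9.24 times the genome rate. Few clusters counted as many peaks do not account for the whole of it, since with peaks within 10 kb counted once its fullest window, at 128 to 129 Mb, held 29 places against a highest random value of 22. The windows at 126 to 127 and 129 to 130 Mb held 21 places each on that count, not above that random value. The random value is the highest of any window in the genome, so staying under it does not show that clusters account for these windows. Stronger sites than elsewhere stay open, because 23.5% of its peaks were strong against 30.4% elsewhere, while 4.63% against 0.916% reached a fold of 100 or more. More copies of the region in both libraries also cannot be told apart from more binding sites: 22.8% of its peaks had an inferred input of 2 or more (22.7% elsewhere, Fisher's exact p = 0.943), 11.7% an input of 5 or more (4.33% elsewhere) and 6.05% one of 10 or more (0.545% elsewhere, p = 1.61e-12), so the answer changed with the input chosen as raised. Neighbouring peaks were counted as independent in these tests.

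The chromosomes differed in peaks per Mb, from 3.23 on X to 13.4 on 17, leaving Y aside. Assembly gaps do not account for the extremes, because all 4 of chromosomes 17, 20, 4 and X stayed on their side over length without gaps (exact binomial test). In the shuffled blocks over that length, chromosome 20 did not pass (adjusted p = 0.0514, permutation test). Gaps could account for the lower call of chromosome 13, which moved from 0.887 to 0.983 times (adjusted p = 0.663, exact binomial test), and 6 further chromosomes gained a call. Unequal copy number of the chromosomes may contribute: across 23 chromosomes without Y, peaks per Mb without gaps rose with the share of peaks with an inferred input of 5 or more (Spearman rho = 0.70, permutation p = 0.00029; Pearson r = 0.711, permutation p = 0.00021; adjusted p = 0.00029 for both, 2 relations computed). Without 17 and X, the pair farthest from the median density, r was 0.75 (permutation p = 8.0e-05). Each listed peak had a fold of at least 13.03, so an inferred input of 5 or more is found only in peaks with many tags. The share therefore also reflects ChIP tag counts and is not a reading of input alone. Gene density and open chromatin, which could give the same relation, were not tested.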

How the results depend on the processing

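Alternatives on chromosome length (without gaps, or to the last peak), blocks, strong shares, dense windows, inferred input and the share of peaks with a neighbour were chosen after the data were seen; the others were planned. With the nuclear peaks among the 11725 better-ranked ones, runs of 2 or more peaks fell to 2082 and dense windows to 27. Fewer peaks entered, and the random limit for windows was 21 in place of 30. The cause of these drops was not tested. At 2 times the lowest fold, 7118 peaks with a median fold of 36.54 were left, by construction. Length without assembly gaps gave 11 chromosomes with more peaks than expected, since it shortens some chromosomes more than others. Shuffled 5 Mb blocks over that same length gave 1 higher and 2 lower, against 11 and 6 there, and the cause was not tested. Chromosomes with a higher or lower share of strong peaks numbered 6 and 4 by tag count in place of fold (cause not tested), and 0 and 0 by Fisher's exact test among the better-ranked peaks, and also at a fold of 100 or more, where the unadjusted p was 0.0116 for chromosome 8 (causes not tested). Merging peaks within 10 kb left 3 dense windows, by counting clusters once. In the chromosome 8 stretch, the raised input was lost at an inferred input of 2 or more (22.8%, Fisher's exact p = 0.943), and the lower share of strong peaks reversed at a fold of 100 or more (4.63%, Fisher's exact p = 3.61e-06); the causes were not tested. Among 144 ratios of single chromosomes under alternatives, 122 kept their side of the threshold, 11 lost and 11 gained a call, and no called ratio changed direction. Of the 122, 19 ratios of 11 chromosomes crossed 1 without a call on either side.

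The share of peaks with a neighbour within 10 kb stayed above the highest random value for all 3 alternatives run (37.1% to 56.4%). No paired analysis was possible because there is 1 library of each kind. Alternatives fixed beforehand on gene position, gene lists, strength at lists and strength by position were not run, as no hg18 annotation was used here. The full depths are unknown, so what depth limits could not be assessed.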

Other observations

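The densities and inputs below were picked out after the values were seen. Some of these inputs also entered the tests of copy number given above, and no further explanation was tested.

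The highest inferred inputs were often found in the chromosome 8 stretch. An input of 5 or more was inferred for 1035 nuclear peaks, of which 33 (3.19%) lay there, and one of 10 or more for 143, of which 17 (11.9%) did. Of the 41 nuclear peaks with an inferred input of 15 or more, 16 (39.0%) lay at 126 to 130 Mb, which holds 1.20% of nuclear peaks. At an input of 20 or more the count was 8 of 16. The 17 peaks of the stretch with an input of 10 or more lay in 9 of its 40 segments of 100 kb. Among single windows, 126 to 127 Mb had the largest share of peaks with an input of 5 or more of the 10 densest windows, 16.7% (95% interval 8.62 to 27.9, adjusted p = 0.00138, Fisher's exact test), while 53 to 54 Mb of chromosome 14 had 1.39% (0.0352 to 7.50).

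Chromosomes 20 and 21 had the largest shares of peaks with an inferred input of 5 or more, 11.9% and 10.2%, and chromosome X, leaving Y aside, the smallest, 0.600%. Several of the highest-ranked peaks packed many tags into 40 bp, such as 338 tags at 128296911 to 128296951 of chromosome 8 and 242 tags at 29824711 to 29824751 of chromosome 2. The peak with 2047 tags was also 40 bp wide. With 1 tag per position and strand, that number needs 1024 bp, and the 5495 tags of the 300 bp mitochondrial peak need 2748 bp. On the same count, the 338 tags need 169 bp and the 242 tags need 121 bp. The span over which tags were counted for a peak, and the treatment of repeated reads, are not given in the sources used here.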
